A study of Mus musculus with 13 samples.

How the data were processed

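Poly(A) RNA from whole hearts of 13 male C57BL/6N mice, 13 weeks old and fed chow, had been sequenced as single-end reads, 1 library per heart. The E3A allele is a knock-in that changes the muscle isoform of carnitine palmitoyltransferase 1 (CPT1B, the enzyme that starts mitochondrial fatty acid entry) so that malonyl-CoA inhibits it less. The groups were WT/WT (4 hearts), WT/E3A (4 hearts) and E3A/E3A (5 hearts), and each file was assigned to its group from the sample labels. The deposited values are read counts per gene symbol, 1 file per heart, with 24061 symbols in each. Per the submitters' processing notes, reads were aligned with STAR 2.4.0 and counted with featureCounts 1.4.4. Strand settings and the treatment of reads that fit several genes or places were not given in the sources used here.

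The files were checked for whole numbers, for identical symbols and for files with identical values (0 found). Depth ranged from 20.1 M to 52.6 M counted reads per library, and 16713 to 17565 genes had at least 1 read. Total counts in the E3A/E3A group averaged 31.8 M reads (SD 8.33, n = 5), in WT/E3A 28.2 M reads (SD 7.47, n = 4) and in WT/WT 39.5 M reads (SD 11.8, n = 4). Standard errors cover the spread between these hearts and counting error only, since reads without molecular identifiers are not independent molecules. Gene positions and lengths came from RefSeq and GENCODE tables of the mouse genome. Of the symbols, 22549 were matched directly, 1352 through an older symbol, 20 had an ambiguous older symbol and 140 had no match; 98.4% had a transcript length and GC content.

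Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by genotype, TMM factors, and a quasi-likelihood F test in 1 fit over the 3 genotypes (estimateDisp and glmQLFit with robust estimation). Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p under 0.05. Comparisons were E3A/E3A against WT/WT, WT/E3A against WT/WT, E3A/E3A against WT/E3A, a slope on the number of E3A alleles, and any genotype difference. Expression is given as CPM after TMM scaling over the libraries of the fit, as mean and SD. Values of single hearts, also in the figures, were scaled over all 13 libraries. Log2 fold changes are edgeR's, with standard errors. Fold changes are first group over the named second group. The level of Cpt1b was also compared with an exact two-sided permutation test on log2 CPM, with 0.1 CPM added. Genes within 5 Mb of Cpt1b were compared with the rest by Fisher's exact test, two-sided.

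The labels describe 4 libraries as potential outliers: WT/WT replicate 1, WT/E3A replicate 1, and E3A/E3A replicates 1 and 2. The primary fit used all 13 libraries, and the same model on the other 9 (3 per genotype) was set beside it. The comparisons, the main tests, the gene lists, the rule for named genes and most alternatives, the 9-library fit among them, were fixed before the data were examined. Sample titles carry a prefix (C2, C3, C4 or C6) whose meaning was not given in the sources used here. It was treated as a possible batch, as a block in the model and by comparison within a prefix. C2 held 2 E3A/E3A and 1 WT/WT library, C3 held 2 E3A/E3A, 1 WT/E3A and 1 WT/WT, C4 held 1 E3A/E3A and 3 WT/E3A, and C6 held 2 WT/WT libraries. With the block the 2 hearts of C6 carry no information on genotype, so comparisons with WT/WT then rest on WT/WT replicates 1 and 2 in the 13 libraries and on WT/WT replicate 2 alone in the 9, a single heart assumed to vary like the others.

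Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry ran beside it, all adjusted over the lists tested in a comparison. List medians are of edgeR's log2 fold changes in the 2 fits reported, and of limma's coefficients on log2 CPM under every alternative, so part of a shift between them can come from the scale (for white adipocyte markers in E3A/E3A against WT/WT, 13 libraries, the medians were -0.50 and -0.26). The 38 lists covered mitochondrial fatty acid oxidation with the carnitine shuttle, PPAR alpha targets, malonyl-CoA and AMPK, fatty acid uptake and storage, glycolysis, pyruvate dehydrogenase, the tricarboxylic acid cycle, oxidative phosphorylation (nuclear genes), mitochondrially encoded mRNAs, peroxisomal oxidation, ketone bodies, branched-chain amino acids, mitochondrial biogenesis, cardiac stress, extracellular matrix, antioxidant genes, the integrated stress response, heat shock proteins, immediate early genes, the circadian clock, sterol and fatty acid synthesis, and interferon response. The rest were markers of cardiomyocytes, endothelium, fibroblasts, smooth muscle, macrophages, lymphocytes, blood, white and brown adipocytes, atrium, skeletal muscle, nerve, epicardium, lung, valve and thymus. The 34 lists with at least 5 tested members were tested. Some lists share members: Acot1, Acaa2, Fabp3, Mlycd, Ucp3, Nppa and Col1a1, for example, stand in more than 1.

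Named genes followed a fixed rule with 3 parts. Part 1 named a set of genes of fatty acid metabolism and cardiac stress in every comparison. Part 2 named, among called genes with a mean of at least 1 CPM, the 10 largest rises and falls against WT/WT (5 and 5 against WT/E3A), or, where fewer than 10 genes passed, all of them and the 10 of lowest unadjusted p. Part 3 named up to 4 members of lowest p in each list that was called or held called genes. Not every gene the rule covers is printed. Etfdh, Hadhb, Hadh, Slc25a20, Ephx2 and Me1 in the 9-library fit fell outside the rule for that fit and were chosen after their values were seen.

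Both fits were tested on simulated data drawn with the means and dispersions of these libraries. With 13 libraries 5 of 67 genes changed by 1.5-fold, 32 of 67 changed by 2-fold and 55 of 66 changed by 3-fold were recovered, with 7 false among 99 calls. With 9 libraries the numbers were 60 of 67, 60 of 67 and 64 of 66, with 23 false among 207 calls. The 39 genes called in the real 9 libraries for E3A/E3A against WT/WT can therefore hold false calls. No shift shared by the 4 potential outlier libraries was simulated, so the recoveries with 13 libraries need not hold for the real data. There 173 genes had an unadjusted edgeR p under 0.05 for E3A/E3A against WT/WT, and 719.35 would be expected by chance. In the comparison simulated without any change, 0 genes were called with 13 libraries and 4 with 9. In the real data 9 libraries gave 3 genes for WT/E3A against WT/WT and 6 for E3A/E3A against WT/E3A, so calls in such numbers can be false. Camera called a list shifted by -0.3 (log2) in 20 of 20 runs with either set of libraries, and called unshifted lists 2 times with 13 libraries and 0 times with 9. The simulated genes were drawn independently, so these runs cannot show how often lists of correlated genes are called falsely. In the real 9 libraries the preset correlation called 16, 7 and 21 lists in the 3 genotype comparisons, and an estimated correlation 0 in each.

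The alternatives fixed in advance were DESeq2 size factors, upper quartile factors, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, sample quality weights, estimation without the robust option, only the 2 groups compared, the 9 libraries, the title prefix as a block, 1 surrogate variable (sva 3.50.0), an absolute log2 fold change of at least 0.5, and each library left out in turn. An offset that removed each library's smooth trend with GC content and length was chosen after seeing the data. So were the same alternatives applied to the 9 libraries, the 9 libraries without 2 that had liver transcripts above 40 CPM, and a clock score (the mean log2 CPM of 10 clock genes, Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Bhlhe41, minus that of 4 others, Arntl, Clock, Npas2 and Nfil3). Splits of the samples into other groups of the same sizes were counted with the same model. To see what shared control libraries give, 20 sets of counts with no genotype difference were simulated. Raw reads were not used here.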

Results

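Transcripts were counted in 13 hearts, 4 WT/WT, 4 WT/E3A and 5 E3A/E3A, to ask whether making CPT1B less sensitive to malonyl-CoA, its physiological inhibitor, changes gene expression in the heart. Total counts were 52.6, 40.2, 23.9 and 41.5 M reads for WT/WT replicates 1 to 4, and 36.1, 20.1, 32.6 and 23.8 M for WT/E3A replicates 1 to 4. For E3A/E3A replicates 1 to 5 they were 42.5, 23.5, 37.0, 32.3 and 23.7 M. The labels describe separate hearts, so the p-values of single genes measure the spread between these hearts. Camera with the preset correlation compares genes inside a list with the rest, so its p-values rest largely on the spread across genes. Fisher's test of nearby genes also counts genes and not hearts. Expression was tested for 14387 genes with all 13 libraries and for 14373 genes with the 9 libraries not described as potential outliers in the labels.

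Reads assigned to Cpt1b, the gene that carries the mutation (chromosome 15, 89416405 to 89425862), did not differ detectably between genotypes. Its mean was 3.18 CPM (SD 0.541, n = 5) in E3A/E3A, 2.65 CPM (SD 0.633, n = 4) in WT/E3A and 2.56 CPM (SD 0.660, n = 4) in WT/WT. For E3A/E3A against WT/WT the log2 fold change was 0.31 (SE 0.22), with an exact two-sided permutation p = 0.214 over 126 splits. The exact p was 0.743 for WT/E3A against WT/WT and 0.222 for E3A/E3A against WT/E3A. In the 9 libraries these exact p-values were 0.1, 1 and 0.1, and 0.1 is the smallest that 20 splits allow. Cpt1b had 1204 reads over all libraries, 53 to 139 in each. A read-through transcript annotated over all of Cpt1b and its neighbour Chkb was listed at 0, and how reads in the overlap were assigned was not given in the sources used here, so whether these reads undercount Cpt1b mRNA was not determined. Cpt2, the next enzyme of the pathway, had 286 CPM in WT/WT and 239.9 CPM in E3A/E3A. Of 66 tested genes within 5 Mb of Cpt1b, edgeR called 0 in each of the 3 genotype comparisons. At an unadjusted p under 0.05 there were 0, 1 and 1 such genes for E3A/E3A against WT/WT, WT/E3A against WT/WT and E3A/E3A against WT/E3A, with Fisher exact p = 1, 0.416 and 0.616. In the 9 libraries edgeR called 0 nearby genes as well, with 6, 2 and 2 at an unadjusted p under 0.05 and Fisher exact p = 0.640, 0.442 and 0.326.

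Cardiac myosin transcripts separated 4 libraries from the other 9. Myh6, the main myosin heavy chain of the adult mouse ventricle, took 9.49% of reads in WT/E3A replicate 1, 9.26% in WT/WT replicate 1, 7.60% in E3A/E3A replicate 1 and 6.59% in E3A/E3A replicate 2, against 3.90 to 4.61% in the rest. The fetal myosin Myh7 reached 1405 CPM in WT/WT replicate 1 and 1342 CPM in WT/E3A replicate 1. Cd36, a fatty acid transporter, stood at 596 and 545 CPM in the same libraries, against 1812 to 2144 CPM in the other WT/WT and WT/E3A hearts. The first principal component held 70.6% of the variance and placed these 4 libraries, the ones described as potential outliers, between -84.2 and -25.5, with the other 9 between 23.6 and 33.2. Both genotype contrasts against WT/WT hold such libraries on either side. The spread between replicates, as the biological coefficient of variation, was 28.9% with 13 libraries and 7.85% with 9.

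**Figure D1:**
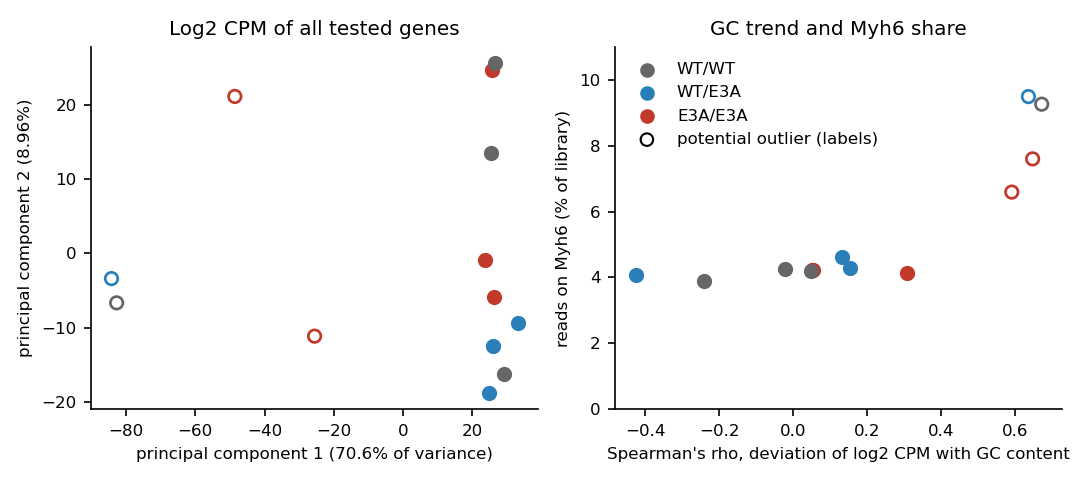
Left, position of each heart's library on principal components 1 and 2 of log2 CPM. Right, percent of reads on Myh6 against Spearman's rho of expression deviation with GC content. Colour gives the genotype and open circles the 4 libraries described as potential outliers, which lie at -25.5 or below on component 1, with the other 9 between 23.6 and 33.2.

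In E3A/E3A hearts compared with WT/WT hearts, which asks what 2 copies of the less inhibited enzyme do, Alox5 fell and the genes of mitochondrial fatty acid oxidation were lower as a group. Alox5, the arachidonate 5-lipoxygenase that starts leukotriene synthesis (chromosome 6, 116410071 to 116461178), had 13.7 CPM (SD 1.65, n = 5) in E3A/E3A and 25.5 CPM (SD 1.72, n = 4) in WT/WT. Its log2 fold change was -0.89 (SE 0.11, edgeR adjusted p = 0.0311), and it was the 1 gene called with 13 libraries. DESeq2 called 24 genes, limma-voom 1, quality weights 73 and a model with 1 surrogate variable 62, and 173 genes had an unadjusted p under 0.05 where 719.35 would be expected by chance. Other genes of low p did not pass. Fbp2, the muscle fructose-1,6-bisphosphatase (chromosome 13, 62836884 to 62858400), had 15.8 CPM (SD 2.39, n = 5) against 31.9 CPM (SD 5.63, n = 4), adjusted p = 0.118 (edgeR). Values for Fah, of tyrosine breakdown, were 13.0 and 20.6 CPM (adjusted p = 0.124), for Acsf2, an acyl-CoA synthetase, 30.3 and 43.0 CPM (adjusted p = 0.270), and for Scn4a, a muscle sodium channel, 44.0 and 65.8 CPM (adjusted p = 0.389). Egf, Scn4b (a sodium channel subunit), Gpam (the first step of glycerolipid synthesis) and Lgals3 (galectin-3) had log2 fold changes of -0.62, -0.97, -0.43 and 0.66 (adjusted p = 0.758 each). Acot3 stood at -0.95. For Acot1, a cytosolic acyl-CoA thioesterase whose close paralogs may share its reads, the means were 7.75 CPM (SD 1.53, n = 5) and 17.0 CPM (SD 6.09, n = 4). It did not pass (edgeR adjusted p = 1). The remaining genes of fatty acid and stress metabolism did not pass either: the log2 fold change was -0.19 for Cpt1a, -0.26 for Cpt2, 0.23 for Acaca, -0.11 for Acacb, -0.27 for Mlycd, 0.02 for Pdk4, -0.57 for Ucp3, -0.25 for Angptl4 and -0.19 for Cd36. It was 0.02 for Slc2a4, 0.15 for Ppara, 0.47 for Ppargc1a, 0.54 for Nppa, 0.32 for Nppb and 0.14 for Myh7. The call of Alox5 ended with the title prefix as a block (-0.87, adjusted p = 0.595; its adjusted p ranged from 2.47e-13 to 0.595 over the other settings), while within prefix C2 (2 against 1 library) the difference was -0.93 and within C3 (2 against 1) -0.78. It also ended without WT/WT replicates 1, 2, 3 or 4 (adjusted p = 0.123, 0.0822, 0.226 and 0.179), WT/E3A replicates 2, 3 or 4 (0.0617, 0.0926 and 0.0873) or E3A/E3A replicates 2, 3, 4 or 5 (0.138, 0.188, 0.193 and 0.149), and it held without E3A/E3A replicate 1 or WT/E3A replicate 1.

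**Figure D2:**
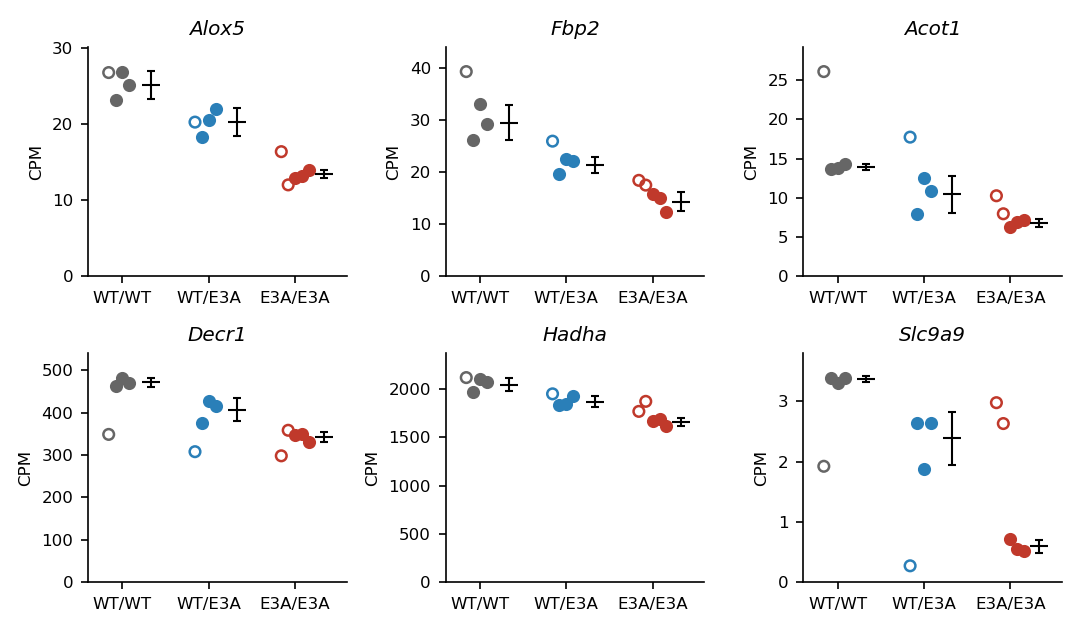
Expression of Alox5, Fbp2, Acot1, Decr1, Hadha and Slc9a9 in each heart (CPM), by genotype. Open circles are the libraries described as potential outliers, and bars give the mean and SD of the filled circles (n = 3). Slc9a9 was at 2.98 and 2.63 CPM in the open E3A/E3A circles and at 0.722 CPM or less in the filled ones.

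Lists of fatty acid, ketone body and branched-chain amino acid metabolism were lower in the same comparison of E3A/E3A with WT/WT hearts. The mitochondrial fatty acid oxidation and carnitine shuttle list fell (24 genes, 23 lower, median log2 -0.18, camera adjusted p = 2.13e-14), and the PPAR alpha targets, genes that this fatty acid receptor switches on, fell with it (19 tested, 17 lower, median -0.27, adjusted p = 1.71e-14). With an estimated correlation these calls held (adjusted p = 0.000677 and 0.000169), and with the prefix as a block the medians were -0.18 (adjusted p = 1.53e-05) and -0.32 (1.4e-06). No member passed in edgeR over all genes tested in either list; adjusted over the list alone, 1 oxidation gene and 2 PPAR alpha targets fell. Among the oxidation genes the log2 values were -0.38 for Slc25a20, the carnitine carrier, -0.26 for Hadha, of the trifunctional protein, -0.22 for Hadh and -0.39 for Decr1, and among the targets -0.20 for Retsat and -0.58 for Acot2. Fatty acid uptake, storage and lipolysis (32 tested, 22 lower, -0.12, adjusted p = 0.000539), peroxisomal oxidation (21 tested, 19 lower, -0.14, adjusted p = 0.00118), ketone body metabolism (7 tested, 6 lower, -0.13, adjusted p = 0.00319) and branched-chain amino acid breakdown (18 tested, 17 lower, -0.09, adjusted p = 0.00319) fell too. These 4 calls held with an estimated correlation (adjusted p = 0.028, 0.022, 0.0325 and 0.028). Adjusted over the list alone, 1 gene fell in the uptake list (Gpam). Without WT/WT replicate 1 the uptake list stood at -0.04 (adjusted p = 0.18) and the peroxisomal list at -0.03 (adjusted p = 0.15), and with the prefix block the ketone and branched-chain lists lost their calls (adjusted p = 0.114 and 0.323). On log2 CPM the ketone median was larger with the block (-0.26, against -0.08 without) and the branched-chain median smaller (-0.04, against -0.08). The uptake and peroxisomal lists kept their calls with the block (adjusted p = 0.000833 and 0.00537). Immediate early genes, which respond within minutes to stimulation, rose as a group (21 tested, 19 higher, median 0.42, adjusted p = 1.97e-11, and adjusted p = 0.0177 with an estimated correlation; prefix block 0.41, adjusted p = 0.00798). Adjusted over the list alone, 1 of its genes rose: Nr4a2, a nuclear receptor, had 10.6 CPM (SD 3.76, n = 5) in E3A/E3A and 4.49 CPM (SD 1.34, n = 4) in WT/WT. Atf3 and Nr4a1 had log2 values of 0.78 and 0.70 and did not pass.

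Markers of other tissues moved in the same comparison of E3A/E3A with WT/WT hearts, with the preset correlation only. Epicardial and mesothelial markers, from the heart's outer lining, rose (7 of 7 higher, median 0.69, camera adjusted p = 8.16e-07; adjusted p = 0.0819 with an estimated correlation; prefix block 0.52, adjusted p = 0.0285), with Upk3b at 1.59. The cardiac stress list rose (16 of 20 higher, 0.14, adjusted p = 0.00111; adjusted p = 0.0896 with an estimated correlation), with Ankrd1 at 0.21; it turned to -0.07 with the prefix block and lost its call without WT/WT replicate 3 (adjusted p = 0.143). White adipocyte markers fell (8 of 8 lower, -0.50, adjusted p = 0.00118; adjusted p = 0.212 with an estimated correlation), with Pck1 at -1.56 and Adipoq at -1.08, and they stood at -0.93 with the prefix block (adjusted p = 1.25e-07) and at -0.08 without WT/WT replicate 1 (adjusted p = 0.926). Atrial markers rose (9 of 10 higher, 0.39, adjusted p = 0.0106; adjusted p = 0.212 with an estimated correlation), but not without WT/WT replicates 1 or 3 (adjusted p = 0.0941 and 0.212) or E3A/E3A replicate 5 (0.182), nor with the prefix block (0.11 on log2 CPM, 0.35 without; adjusted p = 0.574). Weaker calls fell to macrophage markers (0.06, adjusted p = 0.0251; adjusted p = 0.0819 with an estimated correlation), nerve (0.17, 0.0251; adjusted p = 0.137), smooth muscle (0.07, 0.0289; adjusted p = 0.0862), fibroblasts (0.05, 0.0357; adjusted p = 0.0896) and extracellular matrix (median 0.02, mean 0.00, 0.0357; adjusted p = 0.306). Each of these 5 was lost in 5 to 7 fits without 1 library, and with the prefix block (adjusted p = 0.323, 0.0895, 0.828, 0.368 and 0.963). The block changed their medians on log2 CPM from 0.13 to 0.09 for macrophage, 0.21 to 0.26 for nerve, 0.11 to 0.02 for smooth muscle, 0.12 to 0.11 for fibroblast markers and 0.06 to -0.06 for the matrix. Macrophage markers lost their call without E3A/E3A replicates 1, 3 or 5 or WT/WT replicates 1 or 4 (adjusted p 0.0513 to 0.268), and nerve markers without E3A/E3A replicates 1 or 3 or WT/WT replicates 1, 2 or 4 (0.0535 to 0.353). Smooth muscle markers lost it without E3A/E3A replicates 1 or 4 or any WT/WT replicate (0.0624 to 0.175), fibroblast markers without E3A/E3A replicates 1, 3 or 5 or any WT/WT replicate (0.0587 to 0.146), and the matrix list without E3A/E3A replicates 1, 3 or 5 or WT/WT replicates 2, 3 or 4 (0.0532 to 0.39). Lists that were not called had medians of -0.10 for malonyl-CoA and AMPK, 0.02 for glycolysis, -0.03 for pyruvate dehydrogenase, -0.03 for the tricarboxylic acid cycle, 0.00 for oxidative phosphorylation, -0.02 for mitochondrial biogenesis and 0.00 for antioxidant genes (adjusted p 0.183 to 0.838). The integrated stress response stood at 0.07, heat shock proteins at 0.02, the clock at 0.07, sterol synthesis at -0.00 and interferon response at 0.04 (0.111 to 0.426). Markers of cardiomyocytes (0.01), endothelium (0.07), valve (0.13), thymus and cycling cells (0.13), skeletal muscle (-0.05, tested as higher) and lymphocytes (0.04, tested as lower) were not called either (0.135 to 0.712), although the prefix block gave a call for skeletal muscle (-0.38, 0.00537). With under 5 tested members, blood (4 tested), brown adipocyte (4) and lung markers (2) were not tested, and neither were the 13 mitochondrially encoded mRNAs, of which 0 were in the tables.

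When the 4 libraries described as potential outliers were left out (3 hearts per genotype), E3A/E3A hearts had less of many fatty acid oxidation transcripts than WT/WT hearts. edgeR called 39 genes, 8 higher and 31 lower, against 1 with all 13 libraries (1105 at an unadjusted p under 0.05). The 39 became 22 without E3A/E3A replicate 3, 25 without replicate 4, 11 without replicate 5, 10 without WT/WT replicate 3 and 8 without WT/WT replicate 4. Decr1, the dienoyl-CoA reductase needed for unsaturated fatty acids, fell from 499.7 CPM (SD 10.5, n = 3) to 363 CPM (SD 11.1, n = 3), log2 -0.46 (SE 0.05, edgeR adjusted p = 0.00166). Hadha, of the trifunctional protein, fell from 2170 CPM (SD 73.3, n = 3) to 1761 CPM (SD 36.6, n = 3), log2 -0.30 (edgeR adjusted p = 0.0115). Its partner Hadhb (-0.31), Ech1 (-0.39), the thiolase Acaa2 (-0.38), Slc25a20 (-0.35), Etfdh (-0.24), Hadh (-0.25) and Cpt2 (-0.27) fell as well. Acot1 (chromosome 12, 84009502 to 84017670) fell from 14.8 CPM (SD 0.383, n = 3) to 7.25 CPM (SD 0.514, n = 3), log2 -1.03 (SE 0.13, edgeR adjusted p = 0.00405). Fbp2 fell from 31.2 CPM (SD 3.56, n = 3) to 15.2 CPM (SD 1.91, n = 3), log2 -1.03 (SE 0.10, edgeR adjusted p = 0.000866). Alox5 fell by 0.90 on the log2 scale (SE 0.08, adjusted p = 0.000115). Scn4b (-0.93), Fah (-0.65), Plbd1 (-0.63), Egf (-0.61), Scn4a (-0.54), Acsf2 (-0.49), Gpam (-0.41), Fabp3, the heart fatty acid binding protein (-0.31), catalase Cat (-0.28), Ephx2 (-0.33) and Me1 (-0.30) were also among the falls. Slc9a9, an endosomal sodium-proton exchanger, was called at -2.45 (SE 0.19, adjusted p = 6.53e-05), from 3.57 to 0.637 CPM. With the 13 libraries its value was -1.02 and did not pass, since E3A/E3A replicates 1 and 2 had 2.98 and 2.63 CPM and WT/E3A replicate 1 had 0.275 CPM. The rises were Gsg1l (0.42), Lsp1 (0.40), the AP-1 component Jund (0.39, adjusted p = 0.00405), Pi16 (0.39), Gas1 (0.37), the neurotrophic factor Nrtn (0.37), Mesdc1 (0.37) and Zyx, a focal adhesion protein (0.29). With all 13 libraries Jund (-0.07), Nrtn (-0.10) and Mesdc1 (-0.01) had the opposite sign, and their levels in WT/WT replicate 1 were 364, 70.2 and 73.4 CPM. Genes that did not pass with 9 libraries included Nr4a2 (1.21, adjusted p = 0.160), Cpt1a (-0.19, 0.322), Cd36 (-0.19, 0.322), Acot2 (-0.32, 0.107), Nppa (0.69, 0.641) and Myh7 (0.16, 0.480).

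The 39 calls in the 9 libraries depended on single hearts and on the title prefix. Acot1, Fbp2, Alox5, Slc9a9, Decr1, Fah, Scn4a and Jund were called whichever of the 9 libraries was left out. Hadha, Ech1, Acaa2, Fabp3, Cat, Acsf2, Gsg1l, Lsp1, Pi16, Gas1, Nrtn, Zyx, Cpt2, Plbd1 and Egf lost their calls without WT/WT replicate 3 (adjusted p 0.0788 to 0.257), and without WT/WT replicate 4 (0.0894 to 0.356), as did Mesdc1 and Gpam, with Scn4b added for replicate 4. Most of them also lost theirs without E3A/E3A replicate 5 (16 of the genes the rule covers, 0.0549 to 0.156), replicate 3 (13 genes, 0.0597 to 0.154) or replicate 4 (9 genes, 0.0602 to 0.214). Smaller numbers were lost without WT/E3A replicate 4 (6 genes, 0.0504 to 0.0833), WT/E3A replicate 3 (5 genes, 0.0619 to 0.143), WT/WT replicate 2 (4 genes, 0.0555 to 0.132) and WT/E3A replicate 2 (Zyx, 0.0587). With the prefix as a block, where WT/WT replicate 2 is the only informative control heart, 10 genes were called, 5 of them among the 39: Alox5 (-0.83, adjusted p = 0.0155), Fbp2 (-0.91, 0.0201), Acot1 (-1.11, 0.0229), Decr1 (-0.47, 0.0283) and Slc9a9 (-2.39, 0.00925). Within prefix C3 (2 E3A/E3A against the same WT/WT heart, so not independent of the block) the log2 differences were -0.91 for Fbp2, -1.01 for Acot1 and -0.45 for Decr1, and within C2 (2 against 1, all potential outliers) -1.13, -1.52 and -0.09. Hadhb, Slc25a20, Etfdh, Hadh, Ephx2 and Me1, named after their values were seen, were not followed through these settings. The heterozygote mean lay between the means of both homozygous groups for 39 of the 39 called genes. These genes were selected in the same 9 libraries for homozygous means that lie far apart, which favours a heterozygote mean between them. The count expected without a dose effect was not worked out, so 39 of 39 is not evidence of a dose effect.

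As groups, oxidative lists were lower and connective tissue lists higher in the 9-library comparison of E3A/E3A with WT/WT hearts. In the mitochondrial fatty acid oxidation list Cpt1b was the 1 member of positive log2 value. It had 53 to 139 reads per library, and whether these undercount its mRNA was not determined. Of the 24 genes of the list 9 fell and 15 did not pass, and adjusted over the list alone 19 fell. The list median was -0.20 (camera adjusted p = 4.16e-23, adjusted p = 0.0932 with an estimated correlation, fry adjusted p = 0.00799). The heterozygote mean was intermediate for 23 of its 24 genes, but genes are not independent replicates. What no dose effect would give was not worked out. The mean over the list per heart, relative to an arbitrary zero, ran from -0.24 to -0.09 in E3A/E3A, -0.13 to -0.06 in WT/E3A and -0.04 to 0.03 in WT/WT over all 13 hearts. Among PPAR alpha targets 3 of 18 fell, and 12 adjusted over the list alone (-0.19, adjusted p = 1.56e-13). Branched-chain amino acid breakdown (18 of 18 lower, -0.10, adjusted p = 4.22e-09; adjusted over the list alone, 4 fell) and peroxisomal oxidation (-0.08, adjusted p = 1.66e-05) were lower too. For these 3 lists the adjusted p = 0.0932 with an estimated correlation. Fatty acid uptake and storage (2 fell, Gpam and Fabp3; -0.09, adjusted p = 0.000569) and ketone metabolism (-0.14, adjusted p = 0.00949) followed, with adjusted p = 0.155 and 0.125 with an estimated correlation. Extracellular matrix genes had a median of 0.16 (23 of 25 higher, adjusted p = 1.6e-11; adjusted p = 0.186 with an estimated correlation); adjusted over the list alone, 10 rose, such as Col5a1 (0.24), Sparc (0.24) and Fbn1 (0.23). Fibroblast markers were at 0.15 (10 of 10 higher, adjusted p = 2.43e-05; adjusted p = 0.125 with an estimated correlation), and adjusted over the list alone 5 rose, Col1a1 (0.20) and Gsn (0.16) among them. With all 13 libraries the matrix list stood at 0.02 and turned to -0.06 with the prefix block. Immediate early genes (1 rose, Jund; 20 of 21 higher, 0.42, adjusted p = 1.89e-06) and the cardiac stress list (0.14, adjusted p = 0.000439) were higher, with adjusted p = 0.125 and 0.186 with an estimated correlation. Cardiomyocyte markers had a median of 0.03 and were not called. With the prefix block, and so against WT/WT replicate 2 alone, the oxidation list stood at -0.20 (adjusted p = 4.47e-12), the PPAR alpha targets at -0.24 (1.53e-06), the matrix list at 0.10 (1.67e-05) and the cardiac stress list at 0.08 (0.213, call ended). The branched-chain (-0.11, 0.000515), peroxisomal (-0.08, 0.00153), uptake (-0.10, 0.00242), ketone (-0.16, 0.0156), fibroblast (0.12, 0.0071) and immediate early lists (0.39, 0.0184) were also called against that 1 heart. The preset correlation also called 6 lists whose calls single libraries ended. These were the tricarboxylic acid cycle (-0.06, adjusted p = 0.0104; without WT/WT replicates 3 or 4, 0.0506 and 0.13), oxidative phosphorylation (-0.02, 0.039; without E3A/E3A replicate 5 or WT/WT replicate 4, 0.349 and 0.237) and endothelial markers (0.09, 0.018; without E3A/E3A replicate 3 or WT/WT replicate 4, 0.192 and 0.123). The others were macrophage markers (0.12, 0.0319; without E3A/E3A replicates 3 or 5 or WT/WT replicates 3 or 4, 0.0518 to 0.237), atrial markers (0.66, 0.00481; without WT/WT replicate 3, 0.0506) and epicardial markers (0.93, 0.00481; without E3A/E3A replicate 5, 0.0783). With an estimated correlation the adjusted p = 0.553, 0.648, 0.3, 0.324, 0.262 and 0.342. Of these 6, only the epicardial list was called with the prefix block (1.22, adjusted p = 0.0184), and the others stood at -0.01, -0.01, 0.07, -0.06 and 0.08 (adjusted p = 0.802, 0.242, 0.18, 0.941 and 0.14). The block also added calls of interferon (0.23, adjusted p = 5.75e-07), nerve (0.30, 0.0274), glycolysis (0.05), heat shock (-0.31) and lymphocyte lists (-0.37, 0.0416 for each of the last 3).

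**Figure D3:**
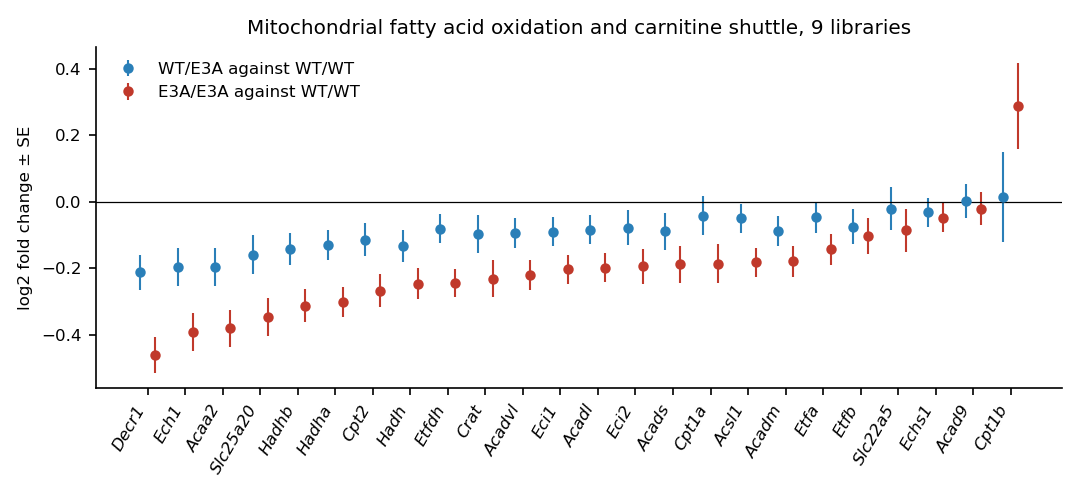
Log2 fold change (with SE) of the 24 members of the mitochondrial fatty acid oxidation list in E3A/E3A (red) and WT/E3A (blue) against WT/WT, 9 libraries, ordered by the E3A/E3A value. Decr1 has the lowest value and Cpt1b is the 1 member above 0 in E3A/E3A. Cpt1b had only 53 to 139 reads in each of the 13 libraries, and whether these undercount its mRNA was not determined.

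In WT/E3A hearts compared with WT/WT hearts, which asks what 1 copy does, clock genes shifted together and sterol synthesis genes were lower. The circadian clock list rose (18 tested, 13 higher, median 0.32, camera adjusted p = 4.72e-07, and adjusted p = 0.00415 with an estimated correlation). Adjusted over the list alone, 5 of its genes rose and 1 fell. The clock output factor Dbp had 34.7 CPM (SD 5.25, n = 4) in WT/E3A and 18.4 CPM (SD 4.35, n = 4) in WT/WT, and Per3, of the period family, 35.8 CPM (SD 6.41, n = 4) and 22.2 CPM (SD 2.54, n = 4). Tef and Ciart had log2 values of 0.44 and 0.81. Arntl (BMAL1), the activator that peaks opposite to these genes, had 18.6 CPM (SD 1.92, n = 4) in WT/E3A and 29.0 CPM (SD 6.30, n = 4) in WT/WT. With the prefix block the clock median was 0.19 (adjusted p = 0.031). Sterol and fatty acid synthesis genes fell as a list (22 of 23 lower, -0.16, adjusted p = 4.72e-07, and adjusted p = 0.012 with an estimated correlation; prefix block -0.13, adjusted p = 0.000892), with -0.37 for Insig1, -0.36 for Sqle and -0.25 for Mvd. Fatty acid oxidation genes fell (22 of 24 lower, -0.10, adjusted p = 0.000145, and adjusted p = 0.0444 with an estimated correlation; prefix block -0.07, adjusted p = 0.0356), a call that ended without WT/E3A replicate 1 (-0.11, adjusted p = 0.0821). PPAR alpha targets stood at -0.07 (adjusted p = 0.0151; adjusted p = 0.0854 with an estimated correlation) and kept their call with the prefix block (-0.13, adjusted p = 0.0249), but lost it without WT/WT replicates 1 or 4 (adjusted p = 0.199 and 0.0691) or WT/E3A replicates 1 or 2 (0.129 and 0.351). No single gene was called by edgeR, and 117 had an unadjusted p under 0.05. DESeq2 and limma-voom called 0, quality weights 5 and the surrogate variable model 3. The 10 genes of lowest p, none passing, were Per3 (0.69), Crmp1 (0.73), Tef, Dbp (0.91), Arntl (-0.64), Esrp2 (-0.89), Ciart, Slc25a1, the mitochondrial citrate carrier (-0.39), Hoxd4 (-0.71) and Arl5c (-0.76). Acot1 (-0.47) and Ppara (0.44) did not pass either. White adipocyte markers (-0.64, adjusted p = 0.000115; adjusted p = 0.258 with an estimated correlation), heat shock proteins (0.26, 0.00256; adjusted p = 0.442), interferon response (-0.12, 0.00625; adjusted p = 0.442) and extracellular matrix (0.17, 0.00787; adjusted p = 0.396) were called with the preset correlation only. The adipocyte list stood at -0.05 (adjusted p = 0.592) without WT/WT replicate 1, and the matrix list at -0.04 (0.934) without WT/E3A replicate 1, with calls also lost without WT/WT replicates 3 or 4 (0.0581 and 0.15). Heat shock proteins lost theirs without WT/E3A replicates 3 or 4 or WT/WT replicate 3 (0.147, 0.314 and 0.133), and interferon genes without WT/WT replicate 1 or WT/E3A replicates 3 or 4 (0.55, 0.0519 and 0.314). With the prefix block heat shock turned to -0.06 (adjusted p = 0.458) and interferon to 0.08 (0.0934), the matrix call ended (0.05, 0.758) and the adipocyte call held (-1.47, 1.35e-12). The other 26 lists were not called, and in 3 of them the median and the mean or the test differed in sign: ketone bodies (median 0.06, mean -0.04), antioxidant genes (median -0.03, mean 0.00) and valve markers (median 0.03, tested as lower). Of the 26, 5 became called with the prefix block: valve (-0.51, adjusted p = 5.96e-05), skeletal muscle (-0.38, 0.000587), lymphocyte (-0.42, 0.00205), thymus and cycling cell markers (0.23, 0.0236) and mitochondrial biogenesis (0.09, 0.0356).

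Clock genes were also the ones called for WT/E3A against WT/WT in the 9 libraries. Hlf, a clock output factor, rose from 25.7 CPM (SD 1.27, n = 3) to 38.5 CPM (SD 3.33, n = 3), log2 0.58 (edgeR adjusted p = 0.00927). Arntl fell from 33.8 CPM (SD 3.65, n = 3) to 19.4 CPM (SD 2.38, n = 3), log2 -0.79, and Npas2, a paralog of its partner Clock, fell from 11.9 CPM (SD 1.16, n = 3) to 7.49 CPM (SD 0.354, n = 3), log2 -0.67 (edgeR adjusted p = 0.0258 each). These 3 were the genes called, with 914 at an unadjusted p under 0.05. Tef (0.47, adjusted p = 0.0504), Mylk4 (0.37, 0.113), Per3 (0.76, 0.163), Itgb6 (-0.29, 0.173), Nr1d2 (0.43, 0.242), Rcan1 (-0.29, 0.242) and Tmem171 (-0.80, 0.276) did not pass. Adjusted over the list alone, 7 clock genes rose and 3 fell (median 0.34, camera adjusted p = 0.0105; adjusted p = 0.639 with an estimated correlation). Oxidation genes (-0.09, adjusted p = 2.61e-07), sterol genes (-0.14, adjusted p = 2.34e-05) and matrix genes (0.10, adjusted p = 5.93e-05) were called only with the preset correlation (adjusted p = 0.676 with an estimated correlation for each). The clock (0.19, adjusted p = 0.268) and sterol calls (-0.11, 0.0598) ended with the prefix block, while the oxidation (-0.10, 0.0017) and matrix lists (0.05, 0.00441) were called, in each case against WT/WT replicate 2 alone. The preset correlation called 7 lists in all, and 11 without WT/E3A replicate 3. The other 3 all lost their calls with the prefix block and had an adjusted p = 0.676 with an estimated correlation. These were PPAR alpha targets (-0.07, adjusted p = 0.00167; block -0.10, 0.0991; without WT/E3A replicate 2, 0.145), heat shock proteins (0.39, 0.00154; block -0.09, 0.473; without WT/E3A replicate 4, 0.0791) and fibroblast markers (0.07, 0.0355; block 0.06, 0.149). The fibroblast call also ended without E3A/E3A replicate 3, WT/WT replicates 2 or 4 or WT/E3A replicate 3 (0.0518 to 0.254). Interferon (0.12), lymphocyte (-0.68) and white adipocyte lists (-0.63, adjusted p = 0.0017 each) and valve markers (-0.53, 0.00226) became called with the block. All 3 gene calls ended with the prefix as a block (Hlf 0.50, adjusted p = 0.912; Arntl -0.61 and Npas2 -0.52, adjusted p = 1 each) and without WT/WT replicates 3 or 4 (adjusted p 0.108 to 0.215 and 0.0718 to 0.234), and Arntl and Npas2 also without E3A/E3A replicate 4 (0.0661) or WT/E3A replicates 2, 3 or 4 (0.0904 to 0.102, 0.148 to 0.181 and 0.0637 to 0.128). The count was 12 without WT/WT replicate 2, 6 without E3A/E3A replicates 3 or 5, 2 without any 1 of the WT/E3A hearts, 1 without E3A/E3A replicate 4 and 0 without WT/WT replicates 3 or 4.

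**Figure D4:**
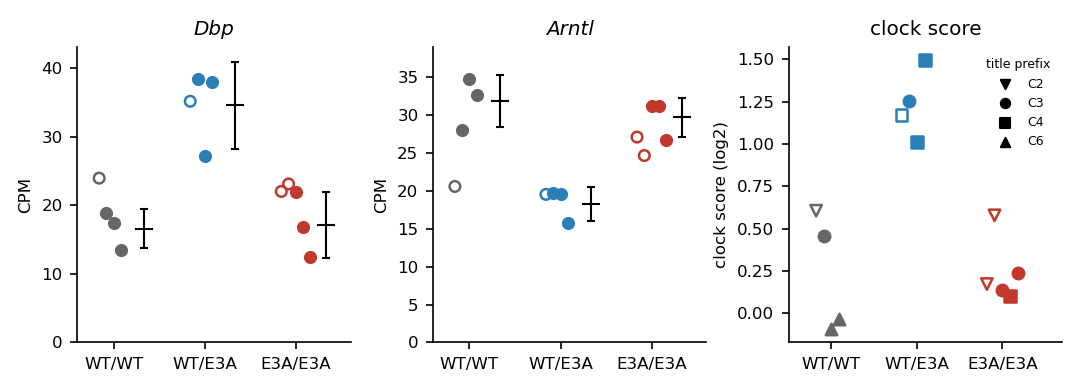
Dbp and Arntl (CPM) and the clock score (mean log2 of 10 clock genes minus that of 4 others of opposite phase) in each heart, by genotype. Open symbols are the libraries described as potential outliers, bars give the mean and SD of the filled ones (n = 3), and the symbols of the score give the title prefix. The 4 WT/E3A hearts have scores of 1.01 to 1.49 and the other 9 lie at 0.61 or below.

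Between E3A/E3A and WT/E3A hearts, which asks what the second copy adds, immediate early genes were higher and PPAR alpha targets lower in E3A/E3A. The immediate early list rose (17 of 21 higher, median 0.47, camera adjusted p = 1.02e-08, and adjusted p = 0.0342 with an estimated correlation; prefix block 0.66, adjusted p = 1.94e-05), and 2 genes rose adjusted over the list alone. Nr4a2 had 10.6 CPM (SD 3.76, n = 5) in E3A/E3A and 2.68 CPM (SD 0.961, n = 4) in WT/E3A (log2 1.98, edgeR adjusted p = 0.693), and Fosb, an AP-1 subunit, stood at log2 2.16. PPAR alpha targets fell (18 of 19 lower, -0.20, adjusted p = 2.08e-05, and adjusted p = 0.0123 with an estimated correlation; prefix block -0.11, adjusted p = 0.00335), with Acot1 at -0.66 and Ucp3 at -0.47. The clock list fell (14 of 18 lower, -0.32, adjusted p = 8.42e-05, and adjusted p = 0.0127 with an estimated correlation) with Dbp at -0.85, Per3 at -0.60 and Arntl at 0.60; adjusted over the list alone 5 fell and 1 rose, and with the prefix block the call ended (-0.17, adjusted p = 0.1). Sterol and fatty acid synthesis genes rose (18 of 23 higher, 0.17, camera adjusted p = 0.000126, and adjusted p = 0.0342 with an estimated correlation, and prefix block 0.14, adjusted p = 0.0062). On log2 CPM the clock and sterol medians were 0.07 and -0.0003 in E3A/E3A against WT/WT, without a call, and 0.31 and -0.16 in WT/E3A against WT/WT. Both calls here use the same WT/E3A hearts as those opposite shifts, so they are not separate evidence of what the second copy adds. No single gene was called by edgeR (lowest adjusted p = 0.693), 208 had an unadjusted p under 0.05, and DESeq2 called 4, limma-voom 0, quality weights 17 and the surrogate variable model 8. The genes of lowest p after Nr4a2 were Alox5 (13.7 and 20.3 CPM, log2 -0.56), Zfp385c (0.97), Gpam (-0.42) and Ciart (-0.85). Called with the preset correlation only were interferon response (0.16, adjusted p = 8.42e-05; adjusted p = 0.151 with an estimated correlation), fatty acid oxidation (-0.10, 0.0019; adjusted p = 0.0585) and nerve markers (0.22, 0.0019; adjusted p = 0.0585). The interferon call ended with the prefix block (0.03, adjusted p = 0.678), and the oxidation (-0.09, 0.00952) and nerve calls (0.35, 0.0438) held. A further 8 called lists also lost their calls without single libraries: epicardial markers (0.52, adjusted p = 0.00387; adjusted p = 0.28 with an estimated correlation), ketone bodies (-0.14, 0.0137; adjusted p = 0.0585), endothelium (0.08, 0.0158; adjusted p = 0.0585) and oxidative phosphorylation (0.06, 0.0243; adjusted p = 0.299), and also mitochondrial biogenesis (-0.07, 0.0354; adjusted p = 0.0868), valve (0.18, 0.0354; adjusted p = 0.28), heat shock (-0.17, 0.0376; adjusted p = 0.497) and fatty acid uptake (-0.08, 0.0479; adjusted p = 0.152). Epicardial markers lost theirs without WT/E3A replicates 1, 2 or 4 or E3A/E3A replicate 5 (adjusted p 0.0529 to 0.217), ketone bodies without WT/E3A replicates 3 or 4 (0.0688 and 0.0617), endothelium without E3A/E3A replicate 1 or WT/E3A replicates 1, 3 or 4 (0.0529 to 0.105) and oxidative phosphorylation without E3A/E3A replicates 1 or 2 or WT/E3A replicates 1, 2 or 3 (0.0682 to 0.38). Mitochondrial biogenesis lost its call without E3A/E3A replicates 1, 3 or 4 or any WT/E3A replicate (0.0506 to 0.158), valve markers without E3A/E3A replicates 1, 4 or 5 or WT/E3A replicates 2 or 4 (0.0506 to 0.665), heat shock without E3A/E3A replicates 1, 3 or 4 or WT/E3A replicates 3 or 4 (0.0506 to 0.756) and fatty acid uptake without E3A/E3A replicates 3, 4 or 5, WT/E3A replicates 1, 3 or 4 or WT/WT replicates 3 or 4 (0.0543 to 0.454). Of these 8, only the valve list kept its call with the prefix block (0.40, adjusted p = 0.0062). The other 7, in the order above, stood at 0.55, -0.09, 0.09, -0.01, -0.08, -0.03 and -0.07 (0.116 to 0.713), and lymphocyte markers became called (0.26, 0.03). The count of called lists, 15, was 9 without WT/E3A replicate 3 and 8 without WT/E3A replicate 4.

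With 9 libraries 6 genes were called between E3A/E3A and WT/E3A hearts, 4 higher and 2 lower, with 993 at an unadjusted p under 0.05. Slc9a9 fell (-1.94, adjusted p = 0.00275) and Alox5 fell from 21.5 CPM (SD 1.97, n = 3) to 14.2 CPM (SD 0.593, n = 3), log2 -0.60 (edgeR adjusted p = 0.0228). Arntl (0.70, adjusted p = 0.0434), Npas2 (0.63, 0.0391), Gm13889 (0.72, 0.0391) and the collagen chain Col5a3 (0.33, 0.0434) rose. Arntl and Npas2 were lower in the same WT/E3A hearts against WT/WT, so their rises here are not separate evidence on the second copy. Nr4a2 stood at 1.77 (adjusted p = 0.163). With the prefix block 2 genes were called, Slc9a9 (-2.02) and Nr4a2 (1.93), with adjusted p = 0.0136 each. Slc9a9 was called whichever library was left out. Arntl, Npas2, Gm13889 and Col5a3 lost their calls without E3A/E3A replicates 3 or 4, WT/E3A replicates 2, 3 or 4, or WT/WT replicates 3 or 4 (adjusted p 0.0561 to 0.338), Alox5 without 5 of these (all but WT/E3A replicate 2 and WT/WT replicate 3), and Col5a3 also without E3A/E3A replicate 5 (0.0787). The count was 2 without E3A/E3A replicate 3, 1 without replicate 4, 13 without replicate 5, 3 without WT/E3A replicate 2, 1 without WT/E3A replicates 3 or 4, 3 without WT/WT replicate 3 and 1 without WT/WT replicate 4. Fatty acid oxidation genes were lower here as well (23 of 24, median -0.12, camera adjusted p = 4.83e-11; adjusted p = 0.18 with an estimated correlation), and adjusted over the list alone 15 fell. The preset correlation called 21 of 34 lists, 10 higher and 11 lower, and an estimated correlation 0. Without WT/E3A replicate 4 the count was 10. Besides the oxidation list, 7 were called whichever library was left out: PPAR alpha targets (-0.14, adjusted p = 1.44e-06), branched-chain amino acids (-0.06, 4.4e-05), ketone bodies (-0.13, 0.00258), sterol synthesis (0.20, 4.02e-06), immediate early genes (0.50, 4.4e-05), endothelium (0.10, 0.00143) and nerve (0.28, 0.00651). These 8 also held with the prefix block. Sterol genes were also called as lower in the same WT/E3A hearts against WT/WT, so their rise here is not separate evidence on the second copy. The other 13 lost their calls without 1 or more of E3A/E3A replicates 3 and 5 and WT/E3A replicates 2 to 4 (adjusted p 0.0507 to 0.51). They were fatty acid uptake, pyruvate dehydrogenase, the tricarboxylic acid cycle, peroxisomal oxidation, mitochondrial biogenesis, cardiac stress, matrix, heat shock, clock, interferon, fibroblast, atrial and valve lists. Calls of the uptake (-0.04, 0.0765), matrix (0.04, 0.0541), heat shock (-0.21, 0.09), clock (-0.30, 0.0841) and fibroblast lists (0.07, 0.117) ended with the prefix block, and lymphocyte markers became called (0.31, 0.0337).

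A slope on the number of E3A alleles was called for Alox5 and Fbp2 when all 13 hearts were used. Such a slope rests almost wholly on the 2 homozygous groups, and WT/E3A hearts enter mainly through the spread around it. The slope per allele was -0.45 for Alox5 (edgeR adjusted p = 0.0202) and -0.51 for Fbp2 (adjusted p = 0.0476), whose WT/E3A mean was 22.5 CPM. This count of 2 became 1 with the prefix as a block. It was also 1 without E3A/E3A replicate 1 or WT/E3A replicates 3 or 4, 4 without WT/E3A replicate 1, 2 without WT/WT replicate 2, and 0 without any other 1 of the 13 libraries. With 9 libraries 38 genes had a called slope, 37 of them among the 39 genes called between the homozygous groups. With 3 hearts per genotype this overlap was nearly fixed by the design and is not separate evidence of a dose effect. The count of 38 was 16 without E3A/E3A replicate 3, 25 without replicate 4, 13 without replicate 5, 10 without WT/WT replicate 3 and 9 without WT/WT replicate 4. It was 15 with the prefix block, 3 at a log2 slope of at least 0.5 and 114 with DESeq2. For any difference between genotypes edgeR called 0 genes with 13 libraries (154 at an unadjusted p under 0.05, DESeq2 20, limma-voom 0, quality weights 71, surrogate variable model 49) and 1 without E3A/E3A replicate 1. With 9 libraries it called 24, with 15 without E3A/E3A replicate 3 or WT/E3A replicates 3 or 4, 11 without E3A/E3A replicate 4, 4 without WT/WT replicate 3 and 5 without WT/WT replicate 4. This count was 7 with the prefix block and 111 with DESeq2.

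Both comparisons against WT/WT use the same control hearts, which makes their fold changes correlate without any genotype effect. Across genes, which are not independent replicates, E3A/E3A and WT/E3A fold changes had r = 0.331 with 13 libraries, where 20 simulations of unchanged groups gave 0.517 (SD 0.00806), and a covariance of 0.00985 against a simulated 0.0531. With 9 libraries r was 0.394 against a simulated 0.478 (SD 0.0286), and the covariance 0.0161 against 0.0197. The simulations drew genes independently, without the shift of the 4 libraries apart on the first component. Their SD therefore does not give the spread that unchanged groups of these hearts would have. With the 4 WT/WT hearts divided 2 and 2 between the comparisons in 6 ways, r ranged from -0.660 to -0.545 on mean log2 CPM, and from -0.640 to -0.491 on edgeR's fold changes. In each division WT/WT replicate 1, at -82.7 on the first component (25.6 to 29.3 in the other WT/WT hearts), stood in 1 control pair only. That heart shifts 1 control mean and not the other, so these r do not show what separate controls alone would give. No gene was called in both comparisons, with 0 in the simulations of 13 libraries and 0.3 on average in those of 9, where chance alone gives 0.00814.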

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

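For the patterns weighed here, the tests of depth and prefix C2 for the 4 libraries, of the cardiomyocyte share, of the prefix in 13 libraries and of differences per heart for the oxidation list, and both tests of the clock score were chosen only after the result was seen, as were the GC and length offset and the score itself. Of 144 groups of 4 or 5 hearts examined for 48 genes and measures, 39 had 1 heart far from the rest by Dixon's test, and most of them were in WT/WT replicate 1 or WT/E3A replicate 1. About 1 in 20, or 7.2, would be expected by chance for independent items not chosen from these data. Many of the genes were called in the 9 libraries, which favours a tight spread there, so 7.2 is no strict expectation. The test looks for 1 heart per group, so the 2 potential outliers of E3A/E3A can mask each other. CPM in these 2 paragraphs were scaled over all genes of the 13 libraries, so last digits can differ from other values scaled over all 13. Values of the 9-library fit were scaled over those 9 alone, which had TMM factors of 1.03 to 1.09 among the 13. A 9-library mean can therefore lie outside a range given here for the same hearts. Against the rest of its own group (range in brackets), WT/WT replicate 1 held 1.59 CPM of Cpt1b (2.83 to 3.00), 26.3 of Acot1 (13.6 to 14.4), 596 of Cd36 (2018 to 2109), 1405 of Myh7 (599 to 677), 364 of Jund (109 to 117), 93.5 of Pi16 (34.2 to 38.0), 60.8 of Gas1 (37.9 to 39.1), 70.2 of Nrtn (16.8 to 17.6) and 73.4 of Mesdc1 (25.1 to 26.7). It also held 1.94 of Slc9a9 (3.297 to 3.391), 16.5 of Plbd1 (40.9 to 47.9), 9.49 of Hlf (23.2 to 25.4), 31.9 of Gm13889 (6.17 to 7.18) and 281 of Col5a3 (70.3 to 76.4).

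WT/E3A replicate 1 stood apart in its group for Acacb, the acetyl-CoA carboxylase that makes malonyl-CoA at the mitochondrion (1081 CPM; others 633 to 681), and Mlycd, which removes it (299; 143 to 145). It also stood apart for Cd36 (545; 1812 to 2144), Myh7 (1342; 624 to 697), Scn4a (70.2; 53.9 to 56.2), Scn4b (76.5; 41.9 to 44.5), Jund (374; 130.2 to 132), Pi16 (115; 42.1 to 46.9), Nrtn (74.5; 17.8 to 18.9) and Mesdc1 (70.7; 27.1 to 29.4). The same held for Zyx (55.7; 64.1 to 64.8), Slc9a9 (0.273; 1.88 to 2.64), Hlf (11.2; 34.0 to 39.9), Npas2 (3.79; 6.75 to 7.41), Gm13889 (26.7; 4.83 to 5.53) and Col5a3 (323; 65.4 to 67.0). Elsewhere, Pdk4, the kinase that shuts down pyruvate oxidation, reached 1146 CPM in E3A/E3A replicate 5 (247 to 356 in the other 4), and the same heart had 202 of Gpam (180 to 181). Acsf2 was at 38.7 in WT/WT replicate 2 (44.1 to 45.2), Arntl at 15.7 in WT/E3A replicate 4 (19.4 to 19.6), and the clock score at 0.58 in E3A/E3A replicate 2 (0.10 to 0.24).

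The first principal component set 4 libraries apart, at -82.7 (WT/WT replicate 1), -84.2 (WT/E3A replicate 1) and -48.6 and -25.5 (E3A/E3A replicates 1 and 2), with Myh6 at 9.26 and 9.49% of reads in the first 2. GC content and length bias was argued against as the whole cause, since removing each library's trend with both left 57.9% of the variance on the component and the 4 libraries 37.9 below the other 9 (49.2 before; the 9 then spanned 3.26). Still, the 4 differed in GC trend (rho 0.590 to 0.671, the others -0.427 to 0.308) and in reads on ribosomal genes (1.06 to 1.27%, the others 0.828 to 0.901%), so library quality stays open as part of it. Low depth was argued against, since 3 of the 4 had more reads than the median of the other 9, and so was title prefix C2 as the cause for all 4, since 1 of the 4 (WT/E3A replicate 1) has prefix C4, whose other libraries lay with the 9, but for the 3 libraries that carry C2 it cannot be told apart, since 0 of the 9 have that prefix. A difference in how these hearts or their RNA were handled, or in the hearts themselves, may explain the separation, and no biological explanation was tested, since the 4 come from all 3 genotypes.

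Fatty acid oxidation genes were lower in E3A/E3A than in WT/WT hearts, with a median of -0.20 and a difference of the list mean per heart of -0.20 (SE over hearts 0.03) in the 9 libraries. Bias by GC content and length was argued against, as with the offset the median was -0.22 and the difference per heart -0.20 (SE 0.03), and so was a lower cardiomyocyte share, as cardiomyocyte markers had a median of 0.026 and per heart lay 0.23 (SE 0.03) above the list. The title prefix was argued against as the whole cause in all 13 libraries. There the difference per heart was -0.15 (SE 0.02) with the prefix as a block and 2 WT/WT hearts informative. Of these 2, WT/WT replicate 1 is a potential outlier. Within C2 it is compared only with 2 E3A/E3A potential outliers (list difference -0.13, and -0.17 within C3). Without it the argument would rest on WT/WT replicate 2 alone. In the 9 libraries the prefix cannot be told apart, as the blocked median of -0.20 rests on WT/WT replicate 2 alone, the heart with the most liver transcripts (69.7 CPM). Lower transcription of this pathway in hearts with a less inhibited CPT1B may explain it, a candidate explanation that was not tested and that these data cannot separate from other differences between 3 and 3 hearts. With an estimated correlation between genes the list had an adjusted p = 0.0932 in the 9 libraries and 0.000677 in all 13.

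Clock genes were shifted in WT/E3A hearts: their clock score differed from that of the other genotypes by 0.99 (SE 0.14, exact p = 0.0014, the smallest that 715 splits allow) in 13 libraries. The title prefix was argued against as the whole cause, since the difference was 1.05 (SE 0.16) with the prefix as a block, 0.97 within C3 (1 against 3 libraries) and 1.123 within C4 (3 against 1). The other hearts were 2 E3A/E3A and 1 WT/WT in C3 and 1 E3A/E3A in C4. Against WT/WT within a prefix, only WT/E3A replicate 2 (1.25) and WT/WT replicate 2 (0.45) can be compared. A part for it stays open, since the clock list against WT/WT was at 0.19 with the block (0.31 without) and lost its call in the 9 libraries (0.19, adjusted p = 0.268), as did Hlf, Arntl and Npas2, and the 2 WT/WT hearts of C6 had the lowest scores (-0.09 and -0.04; 0.45 and 0.61 in the other 2). The potential outlier libraries were argued against, since without them the difference was 1.119 (SE 0.15, exact p = 0.0119, the smallest that 84 splits allow), though the score was formed after the shift was seen, so its p-values describe a hypothesis. A different hour of collection for the WT/E3A hearts may explain it, as may an effect of 1 E3A allele, and neither was tested because the labels give no hour; E3A/E3A hearts, with 2 alleles, had scores of 0.58 or below, against 1.01 or above in WT/E3A.

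Other splits of the hearts into groups of the same sizes were refitted to see what chance gives. With 13 libraries under 5% of the splits, the real grouping included, had as many genes for E3A/E3A against WT/WT (1 gene called, 1 of 100 splits, highest other 0). The same held for the allele number (2 genes, 2 of 100 splits, highest other 6500). This level was not adjusted for the number of counts examined, and the 100 splits were a sample of those possible, so chance is not excluded. With 0 genes called every split has as many, so the splits say nothing about chance for WT/E3A against WT/WT (35 of 35 splits, highest other 0), E3A/E3A against WT/E3A (100 of 100, highest other 1) or any genotype difference (100 of 100, highest other 9765). The splits with 6500 and 9765 genes put the 4 potential outlier libraries into the same group, which points to a structure of the samples larger than genotype. With 9 libraries the share was under 5% for the allele number (38 genes, 1 of 100 splits, highest other 33) and not for any difference (24 genes, 10 of 100, highest other 549). The share for the allele number does not exclude chance for the difference between the homozygous groups, on which the slope almost wholly rests. None of the splits, of 13 or 9 libraries, held the title prefix fixed. With the prefix as a block the 1 and 2 genes of the 13 libraries became 0 and 1 and the 38 became 15, so a part played by the prefix is not excluded for any of these 3 counts. For the pairs of 3 against 3 hearts the 10 splits are too few for a share under 0.05: E3A/E3A against WT/WT had 39 genes (1 of 10 splits with as many, highest other 7), WT/E3A against WT/WT 3 (1 of 10, highest other 0) and E3A/E3A against WT/E3A 6 (2 of 10, highest other 311). The split with 311 genes set E3A/E3A replicates 3 and 4 with WT/E3A replicate 2 against the other 3, which points to a structure among these hearts too.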

How the results depend on the processing

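The GC and length offset, the fit without 2 libraries with liver transcripts and every alternative applied to the 9 libraries were chosen after the data were seen. The lists of fatty acid oxidation, PPAR alpha targets and immediate early genes kept their direction and calls in E3A/E3A against WT/WT in each fit without 1 library, in 13 and 9 libraries alike, but in the 9 all 3 calls ended with an estimated correlation (adjusted p = 0.0932, 0.0932 and 0.125). Alox5, Fbp2, Acot1 and Decr1 were called in the 9 libraries in each leave-one-out fit and under all 9 other settings. Of 5568 gene results with 13 libraries, 5470 stayed on the same side of the threshold, 84 became called and 14 lost a call, and 105 of those that stayed changed sign. Of 4371 with 9 libraries, 4096 stayed, 59 became called and 216 lost a call, and 46 of those that stayed changed sign. Most of these gene results were not called to begin with, so the totals do not measure how stable the calls are. The 14 losses with 13 libraries were all of Alox5, the 1 gene called there, in 11 of 13 fits without 1 library and 3 of 12 other settings. Of 2532 list results with 13 libraries 2249 stayed, 81 became called, 191 lost a call and 11 reversed, and of 1821 with 9, 1593 stayed, 69 became called, 155 lost a call and 4 reversed. The direction of the list test changed in 123 and 85 of these, the reversed ones included. The cause was not tested for the changes below, except that leaving libraries out also lowers their number and that a fold threshold admits fewer genes by construction.

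Gene counts with 13 libraries are given for E3A/E3A against WT/WT (1 in edgeR), WT/E3A against WT/WT (0), E3A/E3A against WT/E3A (0), any difference (0) and allele number (2), in this order and only where they moved. Without the potential outliers they were 39, 3, 6, 24 and 38, with quality weights 73, 5, 17, 71 and 65, and with 1 surrogate variable 62, 3, 8, 49 and 53. DESeq2 gave 24 for the first, 4 for E3A/E3A against WT/E3A, 20 for any difference and 23 for the allele number. The prefix block gave 0 for the first and 1 for the allele number, no filter 0 and 1, the GC and length offset 3 for the first and 1 for any difference, only the 2 groups compared 0 for the first, and a log2 fold change of at least 0.5 gave 1 for the allele number and no value for any difference. Without 1 library each, the counts ranged from 0 to 1, 0 to 0, 0 to 0, 0 to 1 and 0 to 4.

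With 9 libraries E3A/E3A against WT/WT (39) gave 9 at a log2 fold change of at least 0.5, 98 with DESeq2 (38 shared) and 10 with the prefix block (5 shared), and 8 to 43 without 1 library. WT/E3A against WT/WT (3) gave 5 with no filter, 19 with DESeq2, 1 with limma-voom, 1 without the robust option, 0 with the prefix block, 8 without the liver libraries and 0 to 12 without 1 library. E3A/E3A against WT/E3A (6) gave 10 with no filter, 38 with DESeq2, 1 with limma-voom, 1 without the robust option, 2 with the prefix block, 3 with the GC and length offset and 1 to 13 without 1 library. Any difference (24) gave 43 with no filter, 111 with DESeq2, 14 without the robust option, 7 with the prefix block, 37 without the liver libraries and 4 to 34 without 1 library. The allele number (38) gave 3 at a log2 slope of at least 0.5, 114 with DESeq2, 15 with the prefix block and 9 to 42 without 1 library.

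Counts of called lists for the 3 genotype comparisons with 13 libraries (16, 8 and 15) were 7, 3 and 4 with an estimated correlation, 5, 1 and 2 with fry, 8 and 7 against WT/WT and WT/E3A, both for E3A/E3A, with the prefix block, and 11 to 19, 6 to 10 and 8 to 16 without 1 library. With 9 libraries (16, 7 and 21) they were 0, 0 and 0 with an estimated correlation, 6, 0 and 0 with fry, 12 for WT/E3A against WT/WT with limma-voom, and 14 to 21, 6 to 11 and 10 to 25 without 1 library.

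Lists whose test direction reversed with the prefix block in 13 libraries were cardiac stress (median -0.071), extracellular matrix (-0.056) and skeletal muscle (-0.38, adjusted p = 0.00537) in E3A/E3A against WT/WT, heat shock (-0.062) and interferon (0.084) in WT/E3A against WT/WT, and oxidative phosphorylation (-0.011) in E3A/E3A against WT/E3A. In the last it was -0.00098 with quality weights and -0.0022 without the potential outliers, where the matrix list turned to 0.071. Skeletal muscle markers, not called in 13 libraries, were tested there as higher although edgeR's median was -0.05. Without the potential outliers oxidative phosphorylation (-0.021) reversed in E3A/E3A against WT/WT. White adipocyte markers kept a negative median (-0.18) there while the test turned to higher (adjusted p = 0.994). With the prefix block in 9 libraries, where WT/WT replicate 2 is the only informative control, heat shock (-0.31) and macrophage markers (-0.063) reversed in E3A/E3A against WT/WT, and heat shock (-0.087) and interferon (0.12) in WT/E3A against WT/WT. Counting error adds to the spread of genes with few reads such as Cpt1b (53 to 139 per library), and why it had so few was not tested.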

Other observations

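The fit without 2 libraries that held liver transcripts was chosen after the data were seen. Liver transcripts were highest in WT/WT replicate 2 (69.7 CPM over the list, Alb 41.7) and WT/E3A replicate 2 (46.1, Alb 28.5), and without these 2 libraries edgeR called 43 genes between E3A/E3A and WT/WT in the rest of the 9, 28 of them among the 39. Nr4a2, a nuclear receptor induced within minutes by stress hormones, averaged 2.68 CPM in WT/E3A, 4.49 in WT/WT and 10.6 in E3A/E3A.

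Slc9a9 had 2.98 and 2.63 CPM in E3A/E3A replicates 1 and 2, 0.722, 0.556 and 0.524 in E3A/E3A replicates 3 to 5, and 0.275 in WT/E3A replicate 1. These potential outlier hearts lay on the other side from the rest of their genotype, and whether a sample label is wrong was left open. Alox5 in E3A/E3A replicates 1 and 2 was 16.4 and 12.04 CPM, below each WT/E3A (18.3 to 22.0) and WT/WT heart (23.3 to 26.9), and the clock score of WT/E3A replicate 1 was 1.17, within the 1.01 to 1.49 of its genotype. Adult globin genes were listed at 0, and the embryonic Hbb-bh1 had 15 reads in all.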
